A study of Homo sapiens with 12 samples.

How the data were processed

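Poly(A)-selected RNA was sequenced from 12 libraries of 2 established human cancer cell lines, A375 (cutaneous melanoma) and 253J (bladder carcinoma). Per the labels' protocols, each line was incubated with fluorescent 2.4 µm beads for 24 h and sorted by flow cytometry into cells that had taken up at least 1 bead (positive) and cells that had taken up none (negative). The positive and the negative branch were each carried through 5 sorting cycles with 5 generations of growth before each sort. Every line and branch has 3 libraries, numbered 1 to 3 in the labels, and 6 libraries per line entered each fit. Nothing in the labels states whether the 3 libraries of a branch came from separate cultures. Where they share 1 sorted branch, a branch difference unrelated to uptake cannot be told apart from one tied to uptake.

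The deposited unit is a signal, namely gene counts divided by a size factor per library, given as 1 table per cell line with 19423 genes each and values rounded to 0.1. Per the submitters' processing notes, the tools were cutadapt, STAR 2.4.2a, HTSeq and DESeq2 with the GRCh38 genome. The notes as used here give no order, trimming or counting settings, and neither the annotation release nor the strand setting of the counting was given in the sources used here. The size factor of each library was found from the step between its low values, and dividing by that step gave whole reads within 0.055 for 100% of values in each library. The recovered totals were 14576506 to 17916519 reads per library. The size factors equalled DESeq2's median-of-ratios factors computed within each line, so levels are scaled within a line and not between lines. The genes in the tables had all reached at least 6 reads in some library. Gene identifiers were matched to GENCODE release 29 on GRCh38 for positions and gene types, and 99.6% of them matched.

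Because the tables hold normalized values, the main test was limma-trend (limma 3.58.1, R 4.3.3) on log2(value + 1) over genes with a mean of at least 10, with Benjamini-Hochberg adjustment at 0.05 and no covariate. The plan had named edgeR on counts first and this test for the case that the values were normalized, and the second branch was used. Log2 fold changes are positive minus negative on the log2(value + 1) scale, which understates the change of low genes, and folds are taken from them. In addition to the main test, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on the recovered reads. Each line was fitted alone. The difference between lines was the contrast of the 2 within-line differences in 1 limma fit of all 12 libraries, over genes kept in both lines. Overlaps of calls were tested with 2-sided Fisher's exact tests per direction, adjusted over 4 overlaps. A total of 37 gene lists, on uptake, cytoskeleton, adhesion, cell identity, invasion, signalling, metabolism, cell cycle, stress, other cell types and RNA composition, were tested with camera at a preset correlation of 0.01 where at least 5 members were kept, adjusted within each line. That left 33 lists in A375 and 35 in 253J. Camera with an estimated correlation and fry were run beside it.

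Grouping, main tests, gene lists, the rule for naming genes and part of the alternatives were fixed before the data were examined, and the closing section names the tests added later. By that rule the text names, per line, the 8 genes with the largest rise and the 8 with the largest fall among called genes with a mean of at least 50 and no overlap between the 3 positive and 3 negative libraries. It further names a choice from the 2 genes with the smallest p in each list with called members, and, of genes called in both lines, up to 5 changed the same way and 5 changed opposite ways with the largest smaller change. Markers of line identity (MLANA, PMEL, SOX10, KRT7, KRT8, EPCAM) and readouts of uptake (AXL, MERTK, ITGB3, ITGB5, LRP1, CAV1, VIM, LAMP1, CD44) are named whatever their test. The lists gave 55 such genes in A375 and 20 in 253J, of which 26 and 3 are not named. The survey along chromosomes, with medians over protein-coding genes in bins of 10 Mb holding at least 20 genes, was added after the gene tests had been seen, and so were the segment boundaries.

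The labels also give each library a sample number, and these fall into a set of at most 12 and a set of at least 19. In A375, positive replicates 1 and 2 and negative replicate 1 carry low numbers, and in 253J replicates 1 and 2 of both branches do. Within a branch, libraries of the same number set differed by a chi-square per degree of freedom of 1.25 to 1.63, slightly above sampling noise, and libraries of different sets by 7.17 to 17.1. The same-set libraries were kept as separate replicates, and p-values may therefore measure a spread that is partly technical. This weighs most in fits with the number set as a block, where the spread between sets is taken out. What the number sets stand for is not given in the sources used here. For replicate pairing, deviations from the branch means were correlated between same-numbered libraries. In 253J the 3 correlations across genes were 0.286, 0.187 and 0.496, all over 0.1. Of the 6 libraries, 5 correlated best with their own number. Same-numbered 253J libraries also share a number set, however. All pairs across branches within a set gave 0.165 to 0.496, and all pairs across sets -0.371 to -0.25. The check therefore cannot tell pairing by replicate number from the number set. Values with the replicate number as a block are given beside the 253J calls they change for lists and for readouts of uptake.

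Alternatives covered other scalings, filters, pseudocounts, tools, blocks, a fold minimum and leaving out each library in turn. Limma and edgeR calls within each line, with 200 changed genes per line, and limma's difference between lines were first tested on simulated counts. So were camera at the preset correlation and a chromosome median, while the remaining tests across genes were not simulated. For A375, limma called 56.7% of genes changed 1.5-fold, 83.1% of those changed 2-fold and 96.9% of those changed 4-fold, with 13 unchanged genes called among 13909. For 253J the shares were 70.2%, 87.9% and 98.5%, with 13 of 14006 unchanged genes called. For the difference between lines, 88.2% of 229 genes that differed at least 2-fold were called, with 15 false calls. With nothing changed, 0 genes and 0 lists were called in either line. The simulated libraries were drawn independently, without number sets, so these values do not give the false calls to expect in the real libraries. A chromosome 11 shift of 0.3 downward was recovered as -0.299. Plots and tables were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

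Some named genes share reads with others. The counting strand is not known, so reads within overlaps on opposite strands cannot be assigned. This concerns SLC16A3 with CSNK1D (22107 bp), MLANA with KIAA2026, PMEL with CDK2, GPR143 with TBL1X, LRP1 with STAT6, KRT8 with KRT18, SULF2 with NCOA3, RPS25 with TRAPPC4, NDUFB9 with TATDN1, GAS6 with GAS6-AS1, and COL4A1 with COL4A2 (1422 bp). IFITM2 overlaps IFITM1 on the same strand. Near-identical copies also exist for IFITM2, SIRPB1, MGAM2, FTL, KRT8 and the ribosomal protein genes, whose values are uncertain to that extent. SOX10 was not analysed here, and some genes that the rule takes are not reported here.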

Results

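The deposited data compare sorted sub-populations of A375 human melanoma cells and 253J human bladder carcinoma cells that differ in their capacity to take up 2.4 µm beads. The series title relates this capacity to cancer aggressiveness and to cell deformability, and the comparison asks which transcripts differ between the branch kept for uptake (positive) and the branch kept for its absence (negative). Each branch of each line has 3 poly(A) RNA-seq libraries. The recovered depth in A375 was 15035233, 16342961 and 15104467 reads in positive replicates 1 to 3 and 15495527, 15543172 and 15362588 in the negative ones. In 253J it was 14576506, 14777148 and 15164567 reads in positive and 16319307, 17916519 and 15336696 in negative libraries. Levels below are normalized read counts, given as mean ± SD over n = 3 libraries, and adjusted p-values are from limma unless another tool is named.

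The melanocyte antigen MLANA was at 72.0 ± 7.25 in A375 positive and 67.2 ± 26.1 in A375 negative libraries, and lay between 0 and 7.1 in the 253J libraries. The pigment cell protein PMEL was at 2805 ± 294 and 3803 ± 1165 in A375 positive and negative cells, against 72.8 ± 23.3 and 89.1 ± 21.3 in 253J. The simple-epithelial keratin KRT8 stood at 93.6 ± 19.4 and 133 ± 17.0 in A375 and at 8587 ± 274 and 9384 ± 1249 in 253J. KRT7 was at 190 ± 43.1 and 150 ± 11.8 in 253J and at most 2.8 in any A375 library, and EPCAM was at most 6.1 in any of the 12. The 2 tables were scaled separately, so these levels are compared between lines only in order of magnitude. None of these markers passed the test between positive and negative cells (adjusted p 0.76 for MLANA, 0.325 for PMEL and 0.116 for KRT8 in A375; 0.635 for PMEL, 0.466 for KRT7 and 0.637 for KRT8 in 253J). With the sample number set as a block, PMEL (adjusted p = 0.038) and KRT8 (0.0186) passed in A375 and MLANA did not (0.126). PMEL had opposite signs within the low and high set (0.26 and -0.84), and neither PMEL nor KRT8 was among the 52 genes called with same-set libraries averaged to 1 value. That averaged fit has no term for the number set, so the set's effect counts as spread there. It therefore cannot decide about calls gained with the block.

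In A375, bead-positive cells had little left of the collagen chaperone SERPINH1 (HSP47), which fell from 1844 ± 209 in negative to 54.6 ± 4.76 in positive cells (n = 3 each, log2 fold change -5.05 ± 0.11 SE, adjusted p = 9.89e-07). The gene (ENSG00000149257) lies at 75562056 to 75572783 on chromosome 11 of GRCh38, where most genes were lower in positive cells. The heparan sulfate endosulfatase SULF2 on chromosome 20 fell from 157 ± 9.65 to 4.27 ± 2.84, a log2 fold change of -5.12 ± 0.46. In the opposite direction, the matrix proteoglycan versican (VCAN) rose 8.09-fold from 222 ± 46.0 to 1792 ± 208 (adjusted p = 8.98e-05). The transcriptional coregulator MN1 rose 24.4-fold, from 3.97 ± 1.70 to 115 ± 2.41.

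Further rises were seen for the sodium-calcium exchanger SLC8A1 (8.42-fold), the guidance receptor ROBO2 (8.04-fold), the sulfate donor synthase PAPSS2 (7.01-fold), the neural crest transcription factor TFAP2B (6.52-fold) and the dynein intermediate chain DYNC1I1 (6.45-fold). The annotated antisense gene AF121898.3 rose 28.7-fold, from 4.97 ± 3.0 to 159 ± 46.0, but its counts are uncertain because the counting strand is not known. The other large falls were in the homeobox factor CUX2 (18.5-fold), the calcium-binding protein CALB2 (13-fold), COL14A1 (7.20-fold), the ion transport regulator FXYD3 (7.05-fold), MGAM2 (6.73-fold) and SHISA3 (6.50-fold). CALB2 rested on uneven negative libraries (97.9 ± 92.3), at 204.5 in the low-numbered one and 43.5 and 45.8 in the high-numbered ones. Its log2 fold change was -4.38 within the low set and -4.51 within the high set, where the positive library was near the floor. The CALB2 call was lost without positive replicate 2 (adjusted p = 0.0748), negative replicate 2 (0.0603) or negative replicate 3 (0.0642).

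**Figure D1:**
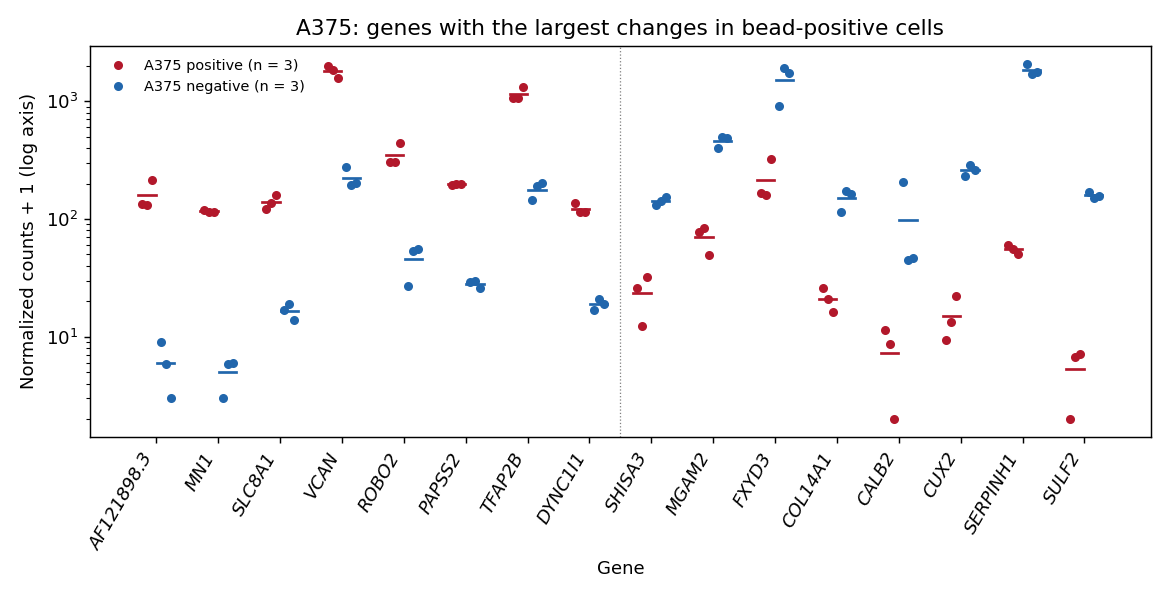
Normalized counts + 1 on a log axis for the 8 genes that rose most and the 8 that fell most in A375 positive cells, with each of the 3 positive (red) and 3 negative (blue) libraries as a point and the group mean as a bar. SERPINH1 stands at a mean of 54.6 in positive and 1844 in negative cells.

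Across the 14118 genes tested for A375 positive versus negative, 1447 passed limma at an adjusted p of 0.05, 704 higher and 743 lower in positive cells, and 343 of them changed at least 2-fold. The positive and negative libraries did not overlap for 29.5% of tested genes, where 3 against 3 exchangeable libraries give 10% by chance. The libraries are not exchangeable, since those of a branch and number set resemble each other, so the chance share here is not known. The sample number sets are unbalanced between the A375 branches, and with the number set as a block the test called 4523. Within a set it called 2830 genes (low numbers) and 2371 (high numbers), where each fit sets 2 libraries against 1 and the lone library is assumed to vary like the others. With same-set libraries averaged to 1 value it called 52, all of them among the 1447, so that no gene gained with the block was called there. The averaged fit has no term for the number set, so it cannot decide about the genes gained with the block. The count fell to 548 without positive replicate 1, 488 without positive replicate 2, 541 without negative replicate 2 and 595 without negative replicate 3.

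Genes of particle uptake were not called as a group in A375. Of 21 tested phagocytic receptors and bridging molecules, 2 fell and 19 did not pass (6 adjusted over the list alone), with a median log2 fold change of 0.09 and a mean of -0.11 (camera adjusted p = 0.971). With the number set as a block 7 rose and 6 fell (camera adjusted p = 0.868). The 2 were the apoptotic-cell receptor MERTK, which went from 249 ± 101 to 79.2 ± 25.9 (log2 fold change -1.59 ± 0.36 SE, adjusted p = 0.0316), and the vitronectin-binding integrin subunit ITGB5, from 5767 ± 364 to 4073 ± 206 (-0.50 ± 0.06, adjusted p = 0.00383). Other readouts of uptake did not pass: AXL was at 692 ± 208 in positive and 1080 ± 334 in negative cells (adjusted p = 0.189), ITGB3 at 1211 ± 308 and 1384 ± 294 (0.611), LRP1 at 2311 ± 298 and 1785 ± 187 (0.076), CAV1 at 4182 ± 1147 and 3150 ± 1263 (0.406) and LAMP1 at 4953 ± 107 and 4778 ± 80.9 (0.531). The intermediate filament protein VIM stood at 64194 ± 750 and 57106 ± 2704 (0.106). With the number set as a block, AXL fell by 0.91 on the log2 scale (adjusted p = 7.53e-15, with -0.85 and -0.97 within the low and high set), and LRP1 (0.46, adjusted p = 1.6e-10), VIM (0.15, 1.12e-04) and CAV1 (0.16, 0.00109) rose, while ITGB3 (0.978) and LAMP1 (0.299) did not pass. None of these genes was called with same-set libraries averaged, a fit without a term for the number set that cannot decide about calls gained with the block. In the blocked fit, in turn, the spread is largely that between same-set libraries, little above sampling noise, so its p-values may be too small. Under the same limit, MERTK fell with the block (adjusted p = 1.55e-08, with -1.03 and -1.55 within the low and high set), as did ITGB5 (3.52e-13) and CD44 (7.34e-09). Without a block, CD44, the hyaluronan receptor on chromosome 11, fell by 0.24 ± 0.06 on the log2 scale (adjusted p = 0.0479). The MERTK call was lost without positive replicate 1 (adjusted p = 0.110), positive replicate 2 (0.104), negative replicate 2 (0.115) or negative replicate 3 (0.123), and that of CD44 without any 1 of the 6 A375 libraries (positive replicates 1 to 3 gave 0.0747, 0.145 and 0.0603, and negative replicates 1 to 3 gave 0.0721, 0.138 and 0.136).

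Actin and adhesion genes changed singly. Of 41 genes of branched actin assembly, 5 rose and 3 fell (8 adjusted over the list alone, camera adjusted p = 0.813), among them the WAVE complex member WASF3, up 1.83-fold to 268 ± 33.8, and the actin elongation factor ENAH on chromosome 1, up 1.26-fold to 5457 ± 78.8. Of 30 actomyosin genes, 2 rose (1 adjusted over the list alone), including the GTPase RHOC on chromosome 1, up 1.25-fold. The list was called higher by camera (adjusted p = 0.0427), but not with an estimated correlation (adjusted p = 0.929). The call also ended without positive replicate 1 (adjusted p = 0.163), positive replicate 2 (0.0996), negative replicate 2 (0.117) or negative replicate 3 (0.164). Of 28 integrins and focal adhesion genes, 3 rose and 3 fell (9 adjusted over the list alone), with the laminin-binding subunit ITGA3 down 1.94-fold from 2146 ± 150 to 1115 ± 216 (adjusted p = 0.00472). Of 34 endocytic genes 2 rose and 2 fell (5 adjusted over the list alone), and of 48 lysosomal genes 5 rose and 3 fell (10 adjusted over the list alone). Among the latter, the cathepsin CTSZ on chromosome 20 fell 1.70-fold.

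Matrix genes changed in both directions in A375. Of 53 tested, 8 rose and 7 fell (18 adjusted over the list alone, camera adjusted p = 0.154), with the fibrillar collagen gene COL5A2 up 4.58-fold from 374 ± 43.4 to 1708 ± 66.8 beside VCAN. Of 23 proteases and inhibitors, 5 rose and 2 fell (9 adjusted over the list alone), among them the metalloproteases ADAM12, up 2.55-fold to 595 ± 35.7, and ADAMTS1, up 4.12-fold to 99.2 ± 4.20. The list was called higher (camera adjusted p = 0.0173), though not with an estimated correlation (adjusted p = 0.525). Of 22 mesenchymal genes 3 rose and 5 fell (14 adjusted over the list alone), with the serine protease FAP up 4.47-fold and fibronectin FN1 down 1.40-fold. All 3 called genes of 8 epithelial ones fell (4 adjusted over the list alone), among them the tight junction gene CLDN4 (3.34-fold) and the desmosomal gene DSP (2.36-fold). The FN1 call was lost without positive replicate 1 (adjusted p = 0.0663), positive replicate 2 (0.0944) or negative replicate 3 (0.0661), and that of CLDN4 without positive replicate 1 (0.0568), negative replicate 2 (0.0692) or negative replicate 3 (0.0686).

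The gene list with the lowest camera p in A375 was that of genes induced by p53. Of 24 tested, 12 rose and 1 fell (16 adjusted over the list alone), with a median log2 fold change of 0.30, and the cell cycle inhibitor CDKN1A (p21) rose 1.78-fold from 1604 ± 89.7 to 2862 ± 209 (adjusted p = 0.000745). The antiproliferative gene BTG2 on chromosome 1 rose 1.44-fold. Camera called the list at an adjusted p of 1.18e-06, whereas with an estimated correlation the adjusted p was 0.525. DNA replication genes had 0 called of 40 (0 adjusted over the list alone), and 1 of 40 mitotic genes fell (1 adjusted over the list alone). With the number set as a block, 20 DNA replication genes fell and 5 rose, and camera called the list lower (adjusted p = 0.00147), though not with an estimated correlation (adjusted p = 0.474). Of 28 immediate early and heat shock genes, which can rise on detachment and sorting, 2 rose and 2 fell (6 adjusted over the list alone, camera adjusted p = 0.982).

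Pigment and identity genes fell in part in A375. Of 19 melanocytic genes 1 rose and 4 fell (6 adjusted over the list alone, camera adjusted p = 0.14). With the number set as a block 4 rose and 7 fell (camera adjusted p = 0.381). The ocular albinism receptor GPR143 fell from 48.4 ± 10.6 to 4.6 ± 2.78, and tyrosinase (TYR), which starts melanin synthesis and lies on chromosome 11, from 70.2 ± 21.9 to 8.93 ± 2.22. Of 21 genes of invasive and undifferentiated melanoma 1 rose and 4 fell (6 adjusted over the list alone, camera adjusted p = 0.377), with the neurotrophin receptor NGFR down 2.76-fold and the activin antagonist FST down 1.69-fold. The class II antigen presentation genes HLA-DRA and CD74 fell 1.88-fold and 1.62-fold, in a list of 21 where 1 rose and 4 fell (5 adjusted over the list alone). The interferon-induced IFITM2, on chromosome 11 and overlapping IFITM1, was counted 2.91-fold lower. The lactate exporter SLC16A3 (MCT4) rose 5.26-fold from 185 ± 16.5 to 976 ± 56.4, with an overlap with CSNK1D on the opposite strand whose reads cannot be assigned. The iron storage gene FTL of the NRF2 list rose 1.38-fold, 3 of its 22 members rising and 1 falling (6 adjusted over the list alone, camera adjusted p = 0.114).

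Of 47 cytosolic ribosomal protein genes in A375, 3 fell (3 adjusted over the list alone), RPS25 (1.33-fold) and RPS3 (1.31-fold) among them, both on chromosome 11. The list was called lower (camera adjusted p = 0.0233), but not with an estimated correlation (adjusted p = 0.929). Its call ended without positive replicate 1 (adjusted p = 0.102), positive replicate 2 (0.0859), negative replicate 1 (0.0749) or negative replicate 2 (0.107). Of markers of other cell types, 1 of 16 leukocyte genes was high enough to be tested and did not pass (1 adjusted over the list alone), and of 7 stromal and vascular markers 1 rose (4 adjusted over the list alone). The latter had a median log2 fold change of 0.42 and were called higher by fry (adjusted p = 0.0144) but not by camera (0.121, and 0.525 with an estimated correlation). In all, 4 lists were called in A375, 0 with an estimated correlation, and 13 with the number set as a block. Camera gained with that block, beside DNA replication, the lists of lysosomal (adjusted p = 0.0291), matrix (0.00517), NRF2 (0.0161) and mitochondrially encoded genes (0.046), which were higher, and of epithelial (0.0291), invasive melanoma (0.00147), YAP (0.00397) and ERK output genes (0.0161), which were lower. Of these, fry without a block also called the NRF2 and epithelial lists (adjusted p = 0.00698 for both), camera with chromosome medians taken out the NRF2 list (0.0286) and camera with the replicate block the ERK output list (0.0397). None of the 13 lists was called in the number-set fit with an estimated correlation (adjusted p 0.304 to 0.833). The count was 2 without positive replicate 1, positive replicate 2 or negative replicate 2, 7 without negative replicate 1 and 8 without positive replicate 3.

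Whole chromosomes differed between the A375 branches. On chromosome 11, 89.2% of 691 protein-coding genes were lower in positive cells, with a median log2 fold change of -0.27 (interquartile range 0.225), and 239 were called lower against 8 higher. All 11 bins of 10 Mb on it had a negative median. Lower too were chromosome 18 from 30 Mb on (median -0.35 over 97 genes) and 20 from 30 Mb on (-0.19 over 217 genes), whereas chromosome 1 (0.16 over 1237 genes) and chromosome 20 below 30 Mb (0.18 over 105 genes) were higher. Chromosome 18 below 30 Mb had a median of -0.03. Averaged per library, positive and negative libraries did not overlap on any of the 5 shifted segments (exact permutation p = 0.1, the smallest that 3 against 3 allows, 2-sided). The same held for 11 of 23 whole chromosomes, chromosome 8 with a median of 0.01 among them, so it does not single these segments out. Camera with an estimated correlation gave adjusted p-values of 0.000321 for chromosome 11, 0.000175 for chromosome 1, 0.0281 for chromosome 18 and 0.0281 for chromosome 20. It also called chromosome 9 (median 0.06, all 9 bins positive, 0.0254) and chromosome 2 (median 0.03, 0.0394), the latter not called at the preset correlation (0.292). Chromosomes 1, 11, 18 and 20 held 44.8% of called protein-coding genes but 20% of those tested. With each chromosome's median taken out, 843 protein-coding genes were called in place of 1368, and 766 were shared.

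**Figure D2:**
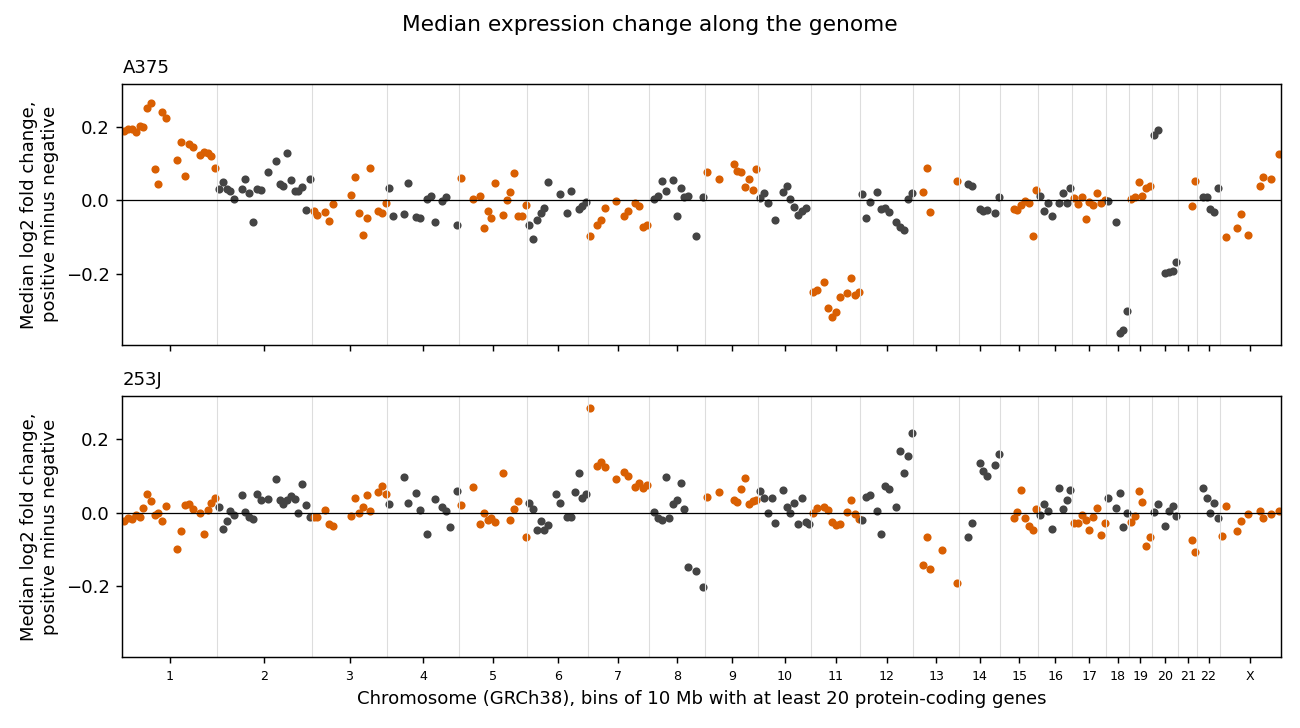
Median log2 fold change (positive minus negative) of protein-coding genes in bins of 10 Mb with at least 20 genes, in order along GRCh38, for A375 (top) and 253J (bottom). In A375 all 11 bins of chromosome 11 lie below 0 and all 22 bins of chromosome 1 above it, and in 253J all 11 bins of chromosome 7 lie above it.

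In 253J, bead-positive cells had a 9.21-fold lower level of the neurotrophin receptor NTRK3, which fell from 335 ± 62.9 to 36.3 ± 11.1 (n = 3 each, log2 fold change -3.20 ± 0.24 SE, adjusted p = 0.000425). The basement membrane collagens COL4A1 and COL4A2, neighbours on chromosome 13 in a region with mostly lower genes, rose 3.07-fold (226 ± 10.2 to 696 ± 8.54, adjusted p = 7.04e-05) and 2.61-fold (315 ± 11.6 to 823 ± 45.5). The small GTPase RAB20, which acts in phagosome maturation and lies on the same chromosome, fell 5.53-fold from 94.1 ± 5.03 to 16.4 ± 3.34 (adjusted p = 0.000539). The lactate exporter SLC16A3 rose 3.48-fold from 211 ± 54.8 to 729 ± 112 (adjusted p = 0.0023), with the same overlap with CSNK1D as above.

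Other large rises were in the matrix gene MAMDC2 (5.74-fold), the short-chain collagen COL8A1 (3.96-fold), the growth factor carrier FGFBP1 (3.32-fold), SIRPB1 (3.21-fold), the filamin-binding adaptor FBLIM1 (3.18-fold) and MYOM3 (3.09-fold). Large falls were in the lipid phosphatase PLPP3 (4.42-fold), the heparan sulfate modifier HS6ST2 (3.92-fold), the adhesion receptor ADGRL3 (3.65-fold), DAW1 (2.98-fold), C1QL1 (2.59-fold) and the semaphorin and VEGF receptor NRP2 (2.55-fold). COL8A1 and SIRPB1 lost their calls without positive replicate 1 (adjusted p = 0.0918 and 0.0713) or positive replicate 2 (0.0996 and 0.0784).

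**Figure D3:**
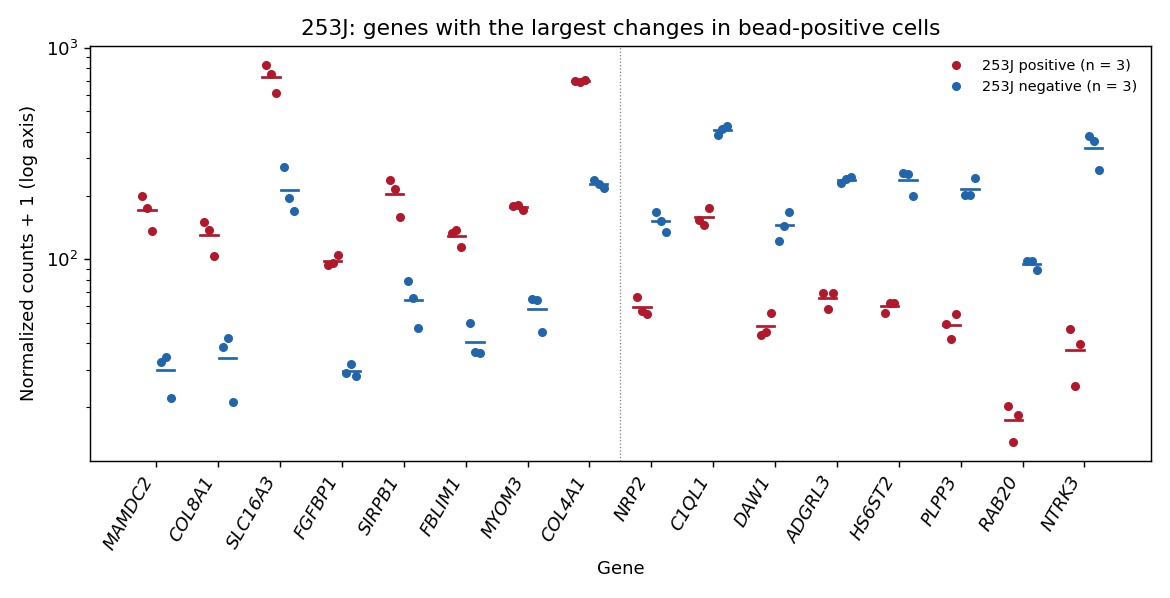
Normalized counts + 1 on a log axis for the 8 genes that rose most and the 8 that fell most in 253J positive cells, with each of the 3 positive (red) and 3 negative (blue) libraries as a point and the group mean as a bar. NTRK3 stands at a mean of 36.3 in positive and 335 in negative cells.

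Across the 14189 genes tested for 253J positive versus negative, 155 passed limma, 75 higher and 80 lower, and 59 of them changed at least 2-fold. The libraries of the 2 branches did not overlap for 20.2% of tested genes, where exchangeable libraries, which these are not, give 10% by chance. With the replicate number as a block, 1991 genes were called, all 155 among them, though the check described cannot show that the numbers pair these libraries. The low-numbered libraries alone gave 2954 and the number-set block 2645, while the high set has 1 library per branch and allows no test. Averaging same-set libraries, in a fit without a block, left 21, all among the 155, and DESeq2 called 301. The count was 43 without positive replicate 1, 39 without positive replicate 2, 75 without negative replicate 1, 54 without negative replicate 2 and 370 without negative replicate 3.

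Without a block, uptake genes were not called as a group in 253J either. Of 22 phagocytic receptors and bridging molecules 1 fell (1 adjusted over the list alone, camera adjusted p = 0.164): GAS6, the ligand of AXL and MERTK, 1.53-fold from 229 ± 16.6 to 150 ± 9.23. With the number set as a block 1 rose and 7 fell, and the list was called lower (camera adjusted p = 0.0443), but not with an estimated correlation (adjusted p = 0.407). AXL itself was at 3297 ± 257 in positive and 3239 ± 479 in negative cells (adjusted p = 0.926), MERTK at 21.3 ± 2.25 and 22.4 ± 9.25 (0.996), ITGB3 at 688 ± 23.3 and 696 ± 47.1 (0.952), ITGB5 at 3328 ± 210 and 3730 ± 262 (0.363) and LRP1 at 1120 ± 202 and 1287 ± 222 (0.605). CAV1 was at 7633 ± 419 and 7684 ± 631 (adjusted p = 0.978), VIM at 37763 ± 2488 and 36867 ± 3951 (0.896), CD44 at 17162 ± 1850 and 15268 ± 2696 (0.615) and LAMP1 at 3717 ± 29.4 and 4343 ± 22.8 (0.0757). Both GAS6 and LAMP1 lie on chromosome 13, where most genes were lower (median log2 fold change -0.13 over 208 protein-coding genes). With the replicate block, LAMP1 (adjusted p = 0.00164), CD44 (0.0168), LRP1 (0.0231) and ITGB5 (0.0434) passed. None of them was called with same-set libraries averaged, a fit without a block that cannot decide about calls gained with one. The membrane remodellers EHD2 and EHD3 fell 1.44-fold and 2.33-fold, the 2 called of 33 endocytic genes (2 adjusted over the list alone). None of 40 branched actin genes (2 adjusted over the list alone) and none of 29 actomyosin genes (0 adjusted over the list alone) passed limma. With the replicate block the branched actin list was called higher (camera adjusted p = 0.0415 in place of 0.0694) and the lysosomal list lower (0.0283 in place of 0.0694), neither with an estimated correlation (adjusted p = 0.531 for both). The talin TLN2, which links integrins to actin, fell 1.68-fold, 1 of 2 called among 26 adhesion genes (3 adjusted over the list alone), and CTSZ rose 1.33-fold, the 1 called of 47 lysosomal genes (3 adjusted over the list alone). The calls of GAS6, EHD2, EHD3 and CTSZ were lost without positive replicate 1 (adjusted p 0.0873 to 0.162), positive replicate 2 (0.0752 to 0.171) or negative replicate 2 (0.0722 to 0.20). EHD3 and CTSZ also lost theirs without positive replicate 3 (0.0512 and 0.10), and GAS6, EHD2 and CTSZ without negative replicate 1 (0.0688 to 0.141).

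Matrix genes changed in both directions in 253J. Of 40 matrix genes 7 rose and 3 fell (17 adjusted over the list alone, camera adjusted p = 0.793), with a median log2 fold change of -0.05 and a mean of 0.05. With the number set as a block 10 rose and 15 fell (camera adjusted p = 0.781). The collagen COL6A1 fell 2.19-fold from 921 ± 199 to 418 ± 73.0. Of 24 proteases and inhibitors 1 fell (6 adjusted over the list alone), the heparan sulfate degrading enzyme HPSE (2.98-fold). Of 17 epithelial genes 2 rose and 1 fell (3 adjusted over the list alone), the rises being the protease inhibitor SPINT2 (2.21-fold, 300 ± 4.87 to 667 ± 32.4) and the tight junction gene CLDN1 (1.37-fold). The connective tissue growth factor gene CTGF (CCN2), a target of YAP and TGF-beta, rose 2.58-fold from 370 ± 73.1 to 942 ± 15.2. The neutrophil chemokines CXCL8 (2.15-fold) and CXCL2 (1.40-fold) rose, the 2 called of 23 inflammatory genes (4 adjusted over the list alone). GPR143 fell 1.76-fold, and the complex I subunit NDUFB9, on chromosome 8 beyond 100 Mb, 1.35-fold. All 7 of COL6A1, HPSE, CLDN1, CXCL8, CXCL2, GPR143 and NDUFB9 lost the call without positive replicate 1 (adjusted p 0.0766 to 0.152) or positive replicate 2 (0.0804 to 0.179), and all but COL6A1 without negative replicate 2 (0.0603 to 0.191). Further losses came without negative replicate 1 for HPSE, GPR143, CXCL2 and NDUFB9 (0.0712 to 0.110) and without positive replicate 3 for GPR143 (0.0711) and CXCL2 (0.0574).

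The calls of MAMDC2, SLC16A3, FGFBP1, FBLIM1, MYOM3, COL4A1, COL4A2, NTRK3, RAB20, PLPP3, HS6ST2, ADGRL3, DAW1, C1QL1, NRP2, TLN2, SPINT2, CTGF, ADGRL2 and PAPPA held in each of the 6 fits without 1 library. These are 20 of the 40 called genes named for this line.

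Small shifts of whole groups were called in 253J. Cytosolic ribosomal protein genes had a median log2 fold change of -0.13 (0 of 47 called singly, 6 adjusted over the list alone, camera adjusted p = 1.48e-13), nuclear respiratory chain genes -0.13 (1 of 46 fell, 3 adjusted over the list alone, 1.84e-09), antigen presentation genes -0.18 (0 of 19, 0 adjusted over the list alone, 0.00013), mitochondrially encoded genes -0.13 (0 of 13, 0 adjusted over the list alone, 0.00197) and NRF2 targets -0.11 (0 of 25, 0 adjusted over the list alone, 0.0061). Higher were NF-kappaB inflammatory genes (median 0.23, 2 of 23 rose, 4 adjusted over the list alone, camera adjusted p = 0.000919), DNA replication genes (0.14, 0 of 40, 0 adjusted over the list alone, 0.000483), genes of invasive melanoma (0.14, 1 of 19 rose, 2 adjusted over the list alone, 0.00741) and YAP targets (0.11, 1 of 24 rose, 2 adjusted over the list alone, 0.0098). With an estimated correlation none of the 9 was called (adjusted p = 0.628 for all but NRF2 targets, 0.764, and DNA replication, 0.802), and fry called 0 lists. With the replicate block 15 lists were called, these 9 among them. The others, besides branched actin and lysosomal genes, were hypoxia (adjusted p = 0.000982 in place of 0.0561), ERK output (0.0462 for 0.188) and mitotic genes (0.0383 for 0.174), which were higher, and the unfolded protein response (0.0383 for 0.237), which was lower. None of the 15 was called in that fit with an estimated correlation (adjusted p 0.531 to 0.789). Mitochondrial transcripts took 8.81% to 9.25% of reads in positive libraries and 9.19%, 9.45% and 10.6% in negative replicates 1 to 3. Without negative replicate 3 the medians were -0.0943 for ribosomal, -0.07 for respiratory chain and -0.08 for mitochondrially encoded genes, 5 lists were called, DNA replication turned direction (adjusted p = 0.967), and NRF2 targets (0.30), YAP targets (0.103) and invasive melanoma genes (0.0766) no longer passed. Leaving out negative replicate 3 keeps the high-numbered set in the positive branch only. In 253J that set by itself had lower DNA replication (median -0.28), YAP (-0.20) and invasive melanoma genes (-0.23) and higher NRF2 targets (0.18). This fit therefore cannot tell these losses from the number set. Without positive replicate 3, which keeps the high set in the negative branch only, 15 lists were called. Markers of other cell types gave 0 called of 2 leukocyte (0 adjusted over the list alone), 0 of 4 stromal and vascular (1 adjusted over the list alone) and 0 of 5 keratinocyte genes (0 adjusted over the list alone).

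Segments also shifted in 253J, and the 5 named first lie on other chromosomes than the 5 shifted segments of A375. Chromosome 7 was higher (median 0.12 over 574 protein-coding genes, 78.8% higher), as were chromosome 12 from 100 Mb on (0.16 over 211) and chromosome 14 from 50 Mb on (0.13 over 280). Chromosome 13 (-0.13 over 208) and chromosome 8 from 100 Mb on (-0.18 over 141) were lower. Per library the branches did not overlap on any of these 5 segments (exact permutation p = 0.1, the smallest possible, 2-sided), nor on chromosome 14 below 50 Mb or on 11 of 23 whole chromosomes, among them 4 and 18 with medians of 0.02 and 0.01. Chromosome 8 below 100 Mb had a median of 0.01 and chromosome 14 below 50 Mb of -0.06. Camera with an estimated correlation gave adjusted p-values of 0.00741 for chromosome 7, 0.0175 for 13, 0.0175 for 14 and 0.0208 for 8, and did not call chromosome 12 (0.0564). It also called chromosome 19 (median -0.04, 0.0208). Chromosomes 21 (median -0.08, 78.4% lower), 9 (0.05) and 17 (-0.03) were called at the preset correlation (adjusted p = 0.000288, 0.00789 and 0.0343) but not with an estimated one (0.0564 for each). On the 5 segments named first for 253J the A375 medians lay between -0.04 and 0.00. On the 5 shifted segments of A375 the 253J medians lay between -0.01 and 0.01. Chromosome 9, however, was higher in both lines, with medians of 0.06 in A375 and 0.05 in 253J and all 9 bins positive in each. Its median difference between lines was 0.0088 and was not called (camera adjusted p = 0.853).

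The lactate exporter SLC16A3 rose in bead-positive cells of both lines. Of 25 genes called in both, 13 changed the same way and 12 opposite ways. The same-direction genes with the largest changes were this gene, the phosphodiesterase PDE7B (3.56-fold higher in A375 and 3.57-fold in 253J), the pregnancy-associated protease PAPPA (2.50-fold and 2.67-fold higher), the chromodomain gene CDYL2 (2.15-fold and 2.21-fold lower) and the adhesion receptor ADGRL2. ADGRL2 rose from 246 ± 13.8 to 718 ± 22.3 in 253J. In A375, where it lies on the higher chromosome 1, it had 112 reads in positive and 1 read in negative libraries, a ratio of 112 with an exact 95% counting interval of 19.8 to 4479. Opposite changes were led by FBLN1 (3.57-fold lower in A375, 3.06-fold higher in 253J), PRR5L (2.14-fold higher in A375, on chromosome 11, and 4.68-fold lower in 253J), the ERK phosphatase DUSP9 (3.08-fold higher and 1.91-fold lower), the microfibril gene FBN2 (7.24-fold lower and 1.91-fold higher) and PAPSS2 (7.01-fold higher and 1.67-fold lower).

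Several of these calls were lost in fits without 1 library, most of them whichever of several libraries was left out. In A375, PAPPA (adjusted p 0.143 to 0.158), CDYL2 (0.0507 to 0.0705) and PRR5L (0.152 to 0.169) lost theirs without positive replicate 1 or 2 or negative replicate 2 or 3, and FBLN1 without positive replicate 2 (0.0829). In 253J, PDE7B, CDYL2, PRR5L, DUSP9, FBN2 and PAPSS2 lost theirs without positive replicate 1, positive replicate 2 or negative replicate 2 (adjusted p 0.0633 to 0.164). Without positive replicate 3, PDE7B, PRR5L, DUSP9 and FBN2 were lost too (0.0522 to 0.109), as were CDYL2, DUSP9, FBN2 and PAPSS2 without negative replicate 1 (0.0656 to 0.147). FBLN1 was lost without positive replicate 1 or 2 (0.0802 and 0.0804).

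Among 12509 genes tested in both lines, 9 were called higher in both where independent lists give 2.46 (odds ratio 4.24, Fisher's exact p = 0.000674, adjusted p = 0.0027), and 4 lower in both where 3.02 are given (adjusted p = 0.545). A further 7 were higher in A375 and lower in 253J (2.83 given, adjusted p = 0.0442) and 5 the reverse (2.63 given, adjusted p = 0.251). Fisher's test takes genes as independent, which they are not, so these p-values may be too small. An overlap passed in the same and in an opposite direction, so it does not by itself show a shared direction. Across genes, which are not independent replicates, the log2 fold changes of the 2 lines correlated with r = 0.0467 (Spearman 0.048). The difference between lines in the positive versus negative effect was called for 770 genes, led in size by SULF2 (-4.97 ± 0.49 SE, A375 minus 253J, adjusted p = 7.51e-05) and SERPINH1 (-4.84 ± 0.13, adjusted p = 2.13e-10), and for 3504 with the number-set block. That count was 488, 484, 484 and 512 without A375 positive replicates 1 and 2 and negative replicates 2 and 3, and 448, 444 and 500 without 253J positive replicates 1 and 2 and negative replicate 2. The 13 shared same-direction calls were 8 without any 1 of those 4 A375 libraries, 4, 3, 6 and 4 without 253J positive replicates 1 and 2 and negative replicates 1 and 2, and 28 without 253J negative replicate 3.

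**Figure D4:**
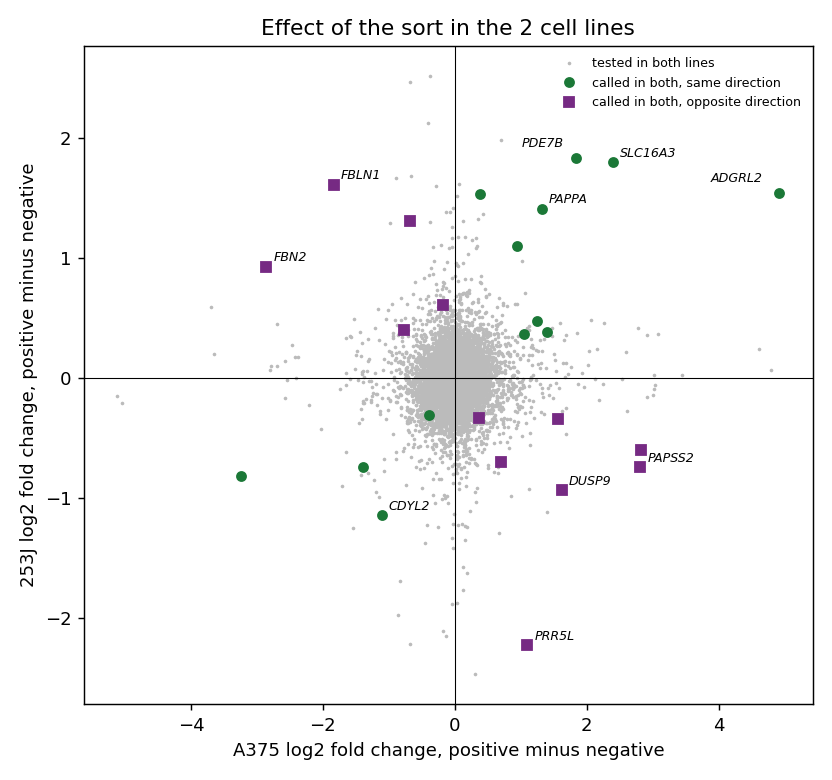
Log2 fold change (positive minus negative) in 253J against A375 for each of the 12509 genes tested in both lines (grey), with the 13 genes called in both in the same direction as green circles and the 12 called in opposite directions as purple squares. The cloud shows little slope, with r = 0.0467 across genes.

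**Figure D5:**
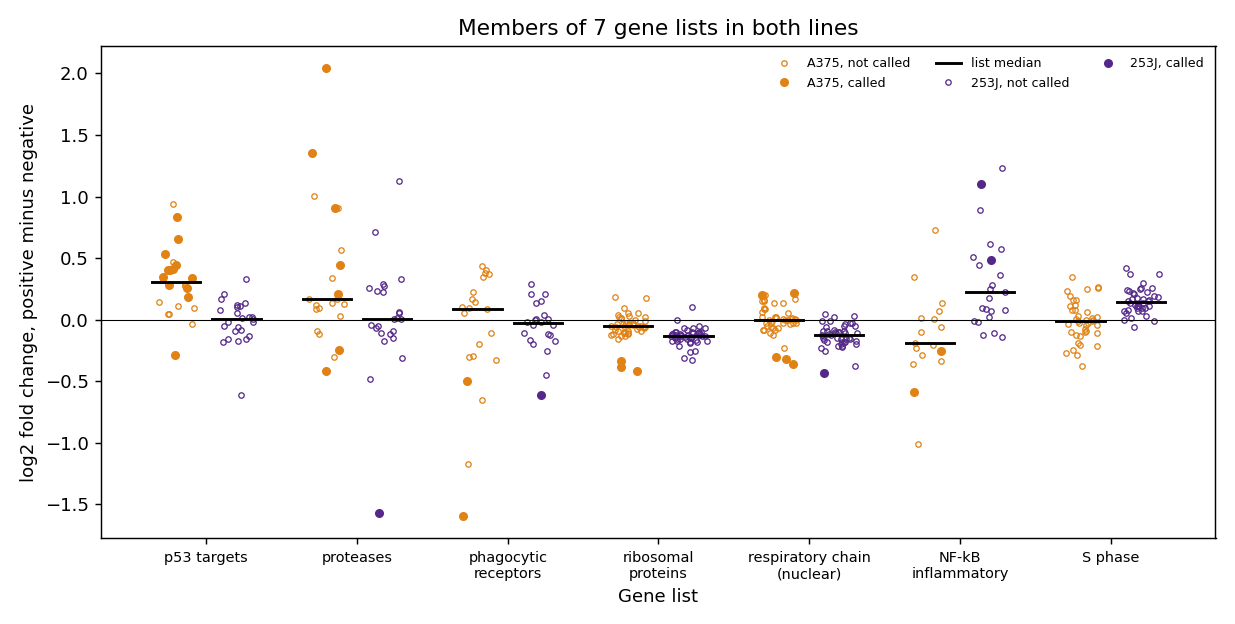
Log2 fold change (positive minus negative) of each tested member of 7 gene lists in A375 (orange) and 253J (purple), with called genes filled, other genes open and the list median as a black bar. The p53 targets have a median of 0.30 in A375 and 0.01 in 253J, and the ribosomal protein genes -0.05 and -0.13.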

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

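The regression and number-set tests of the chromosome shifts and both tests of the p53 list were chosen only after the result was seen, as were the interval used to read the noncoding genes, the chromosome survey, TMM and total-read scaling, the fits of single number sets, and the splits kept within number sets.

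What stands out here is a positive minus negative difference that is not the same in A375 and 253J, by limma's test of the difference itself. It passed for 770 of 12509 genes, and 3 of 100 splits of the libraries within each line gave as many (highest other split 1327). Both others divide the A375 libraries along the number sets, so they carry the difference between the sets. The test was therefore repeated with the number set as a block, for which the real value is 3504, over 100 of the 108 splits that keep each set's positive and negative numbers. In it 1 of 100 splits gave as many. The 9 other splits with A375 as in the labels gave 1120 to 3387, and the remaining 90 at most 152, so the test responds mainly to the A375 grouping. Same-set libraries of a branch differed little more than sampling noise, so neither set of splits decides about chance. The count for the difference between lines in the positive versus negative effect was 444 without 253J positive replicate 2, the lowest without 1 library. All differences below are A375 minus 253J on the log2 scale. Among genes with large changes in A375, the difference was 4.37 for MN1, 2.70 for SLC8A1, 2.99 for VCAN, 3.14 for ROBO2 and 3.55 for PAPSS2, and -4.97 for SULF2, -4.84 for SERPINH1, -4.29 for CALB2 and -3.16 for SHISA3. It was 3.38 for ADGRL2, a value that depends on the pseudocount because A375 negative libraries held 1 read, -3.45 for FBLN1, 3.33 for PRR5L, 2.55 for DUSP9 and -3.79 for FBN2. Adhesion and cytoskeleton genes gave 0.85 for WASF3, 0.34 for RHOC, -1.09 for ITGA3 and 0.65 for TLN2, and endocytic genes 0.61 for EHD2 and 1.27 for EHD3. Lysosomal genes gave -1.18 for CTSZ and 0.28 for LAMP1. Matrix and protease genes gave 2.37 for COL5A2, 1.02 for ADAM12, 1.81 for ADAMTS1, -1.55 for COL4A1, -1.46 for COL4A2, 1.11 for COL6A1 and 1.70 for HPSE.

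The remaining genes with such a difference were NRP2 (1.51), HS6ST2 (1.11), CLDN4 (-1.65), GPR143 (-2.42), CDKN1A (0.85), BTG2 (0.55), CD74 (-0.60), FTL (0.75), MAMDC2 (-2.89), SIRPB1 (-2.34), FBLIM1 (-2.55), RAB20 (2.77), PLPP3 (2.02), C1QL1 (0.93) and NDUFB9 (0.41). Of the gene lists, the median difference was 0.30 for p53 targets, 0.13 for nuclear respiratory chain genes, 0.18 for mitochondrially encoded genes, 0.069 for ribosomal protein genes, 0.21 for NRF2 targets and 0.11 for proteases. It was -0.23 for inflammatory genes, -0.15 for DNA replication genes, -0.13 for mitotic genes and -0.15 for genes of ERK output. None of these 10 list differences was called with an estimated correlation (adjusted p 0.505 to 0.831). Of the chromosomes, the median difference was 0.17 for chromosome 1, -0.16 for 7, -0.26 for 11, -0.077 for 12, 0.13 for 13, -0.26 for 18, -0.11 for 20 and 0.0976 for 21, and these 8 kept their call with an estimated correlation (adjusted p 0.000147 to 0.0241).

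For the calls within each line, 3 libraries against 3 make 10 splits, too few for a share under 0.05. In A375 the real split gave 1447 genes and 2 of 10 splits gave as many, the other being the split that follows the sample number sets (1670 genes). For A375 positive versus negative, the set-blocked count was 4523. In 253J the real split gave 155 genes, 1 of 10 splits as many, and the highest other gave 0, which includes the 3 others that part all 3 replicate pairs. For gene lists, all 10 of 10 splits in A375 gave at least the 4 lists of the real split (highest other 12), and in 253J 4 of 10 gave at least 9 (highest other 16), while the 3 others that part all pairs gave 6, 6 and 7.

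The first pattern weighed is the shift of whole chromosomes in A375, where for chromosome 11 bias from gene length, GC content or expression level is argued against, since with these regressed out its median was -0.257, and so are the number sets, where the higher of the 2 within-set medians was -0.276. A different copy number between the branches may account for the shifts, and would move noncoding genes alike. On chromosome 11 their median was -0.145 over 81 genes, against -0.0142 over 1883 noncoding genes elsewhere, but its bootstrap 95% interval of -0.259 to -0.0491 spans the bound of -0.1 set beforehand. Elsewhere the noncoding medians were -0.256 on 18 from 30 Mb (21 genes), -0.189 on 20 from 30 Mb (40 genes), 0.119 on chromosome 1 (200 genes) and 0.00915 on 20 below 30 Mb (19 genes, against 0.18 for coding genes). No DNA data were analysed here, so copy number cannot be told apart from a change in regulation between bead-positive and bead-negative cells, which stays untested.

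The second pattern is the higher level of p53 targets in A375 positive cells. Location on the shifted chromosomes is argued against, as the list median was 0.284 with each chromosome's median taken out, although 7 of its genes were then called higher and 0 lower, in place of 12 and 1. Dependence on 1 number set or 1 library is argued against as well, the lowest of these medians being 0.229. The list's camera adjusted p in the real split was 1.18e-06, with 10 splits in all. Other splits called it too, at 5.33e-04, 5.66e-04, 0.00441, 0.00459 and 0.0339, while the rest gave 0.194 to 0.556. A call of this list is therefore not particular to the real split, though its p was lowest there. With an estimated correlation the list was not called (adjusted p = 0.525). A difference in p53 activity between the sorted branches may underlie it and was not tested.

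The third pattern is the lower level of ribosomal protein genes in 253J positive cells. Negative replicate 3, which had the highest mitochondrial share, is argued against as the whole cause, since the list median without it was -0.0943. With TMM and total-read scaling the higher median was -0.124, but these moved the median of all genes by at most 0.0094 and decide nothing, so scaling stays open. Other splits of the same 6 libraries also called this list, at camera adjusted p-values of 3.61e-08, 2.43e-07, 4.43e-07, 1.33e-05, 6.81e-04 and 0.00243, while the rest gave 0.262 to 0.527. With an estimated correlation the real split did not call it (adjusted p = 0.628), so correlated shifts of these genes between libraries may contribute. A difference between the sorted branches stays open and untested.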

How the results depend on the processing

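Tests chosen only after the data were seen are edgeR on recovered reads without and with the number-set block, TMM and total-read scaling, averaged number sets, single number sets, chromosome medians taken out, all segment medians, and the blocks and left-out libraries for the overlap between lines.

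Counts of called genes for A375 positive versus negative (1447) stayed within 1.5 times under other scalings, filters, pseudocounts and tools and in 1 fit of all 12 libraries (1261 to 1573). They moved to 343 with a 2-fold minimum, 2429 with the replicate block, 4523 with the number-set block, 4573 with edgeR and that block, 2830 and 2371 in the low-numbered and high-numbered libraries alone (2 against 1, the lone library being assumed to vary like the others), and 52 with same-set libraries averaged. Without a block, edgeR on the recovered reads called 1461 genes here and 163 for the other line. Leaving out 1 library gave 488 to 1878, and 433 genes kept their call in every such fit. For 253J positive versus negative (155) the count was 59, 1991, 2645, 2723, 2954 (low numbers) and 21 under the same settings, 301 with DESeq2, and 39 to 370 without 1 library, with 37 genes kept in every fit. The difference between lines in the positive versus negative effect (770) moved to 2032 with the replicate block, 3504 with the number-set block, 85 with averaged sets and 444 to 916 without 1 library. Apart from fewer libraries or a stricter criterion where these apply, the cause was not tested.

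The check of pairing behind the replicate block could not tell pairing from the number sets in 253J. In A375 the correlations of same-numbered deviations were 0.415, -0.272 and 0.397, and only replicate 2 joins different sets. The numbers were not taken as pairing the A375 libraries, and 3 of 6 libraries correlated best with their own number. Beyond the counts given, the block left 4 lists called in A375, of which 3 were the same, as the ribosomal list ended at an adjusted p of 0.0552. It gave 15 in 253J, and 193 same-direction calls between lines.

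Lists called in A375 (4) became 0 with an estimated correlation, 7 with fry, 13 with the number-set block and 2 to 8 without 1 library. In 253J (9) they became 0 with an estimated correlation, 0 with fry, 16 with the number-set block and 5 to 15 without 1 library. DNA replication genes reversed in 253J without negative replicate 3 (adjusted p = 0.967, lowest without another library 1.35e-07). That fit keeps the high-numbered set in the positive branch only, so it cannot tell the branch from the set. The overlap of calls between lines (13 in the same direction) became 5 with a 2-fold minimum, 441 with the number-set block and 3 to 28 without 1 library. The correlation across genes of the 2 lines' log2 fold changes (0.0467) was 0.010 with the number-set block and 0.0207 to 0.0771 without 1 library. The cause was not tested.

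The other reversals were of genes that limma had not called and of 2 segments near 0. Where 1 left-out library gave the reversal, the value in brackets is the opposite end of the range without 1 library. MLANA in A375 was at -0.13 without negative replicate 1 (0.44), PMEL in A375 at 0.26 in the low-numbered libraries, and ITGB3 in A375 at 0.0013 with edgeR and the number-set block and 0.0124 in the high-numbered libraries. AXL in 253J was at -0.0213 without positive replicate 1, -0.0911 without negative replicate 3 and -0.0332 in the low-numbered libraries (0.12). MERTK in 253J was at 0.0697 without positive replicate 2, 0.296 without negative replicate 1, 0.0941 with averaged sets and 0.00521 with total-read scaling (-0.24). ITGB3 in 253J was at 0.0125 without positive replicate 1, 0.0380 without negative replicate 3 and 0.0293 in the low-numbered libraries (-0.056), and VIM in 253J at -0.0540 without negative replicate 3 (0.094). CAV1 in 253J was at 0.0335 without positive replicate 2, 0.0285 and 0.0264 without negative replicates 1 and 2, 0.0470 with averaged sets and 0.00189 with total-read scaling (-0.078). Chromosome 18 below 30 Mb in A375 was at 0.00268 in the low-numbered libraries, and the median of chromosome 8 from 0 to 100 Mb in 253J at -0.00195 without positive replicate 2 and -0.00449 without negative replicate 3 (0.034). The cause was not tested. Over all alternatives, 1110 values of the 52 called A375 genes named kept direction and call and 75 lost the call, and for the 40 in 253J these were 760 and 113. At 14576506 to 17916519 reads per library, genes with a mean under 10 were left untested.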

Other observations

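The tests in this part were chosen only after the result was seen.

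The sample number sets carry a broad expression difference of their own in both lines, with the branch held as a term. Cholesterol synthesis genes were higher in the high-numbered libraries, by a median of 0.47 on the log2 scale in A375, where 20 of 24 rose and 0 fell, and by 0.19 in 253J, where 13 rose and 1 fell. DNA replication genes were lower, by a median of -0.29 in A375 (35 of 40 fell) and -0.28 in 253J (38 of 40 fell), and so were YAP targets, by -0.50 (18 of 25 fell, 1 rose) and -0.20 (12 of 24 fell, 3 rose). Nuclear respiratory chain genes were higher by 0.12 (27 of 46 rose) and 0.13 (23 of 46 rose), and lysosomal genes by 0.18 (25 of 48 rose) and 0.10 (17 of 47 rose). Lower in the high-numbered libraries were also actomyosin genes, by -0.19 (21 of 30 fell, 2 rose) and -0.14 (15 of 29 fell, 2 rose), genes of invasive melanoma, by -0.19 (11 of 21 fell, 3 rose) and -0.23 (10 of 19 fell, 2 rose), and genes of intermediate filaments, by -0.22 (8 of 12 fell, 2 rose) and -0.18 (9 of 14 fell, 1 rose). Camera called these 8 lists in both lines (adjusted p 4.6e-20 to 0.0294), but none with an estimated correlation (adjusted p 0.0806 to 0.636).

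Other lists were called for the number set in 1 line and not in the other, and the difference between lines was not tested for them. Among these, melanocytic genes were higher in the high-numbered A375 libraries (median 0.38, 15 of 19 rose). Hypoxia and glycolysis genes (median -0.24, 27 of 35 fell) and inflammatory genes (-0.37, 16 of 23 fell) were lower in the high-numbered 253J libraries. None of these 3 was called with an estimated correlation (adjusted p = 0.350, 0.269 and 0.269). Across 12509 genes, which are not independent replicates, the number-set effect correlated between the lines with r = 0.382 (Spearman 0.420). The positive versus negative difference gave r = 0.0467. Genes called for the number set in both lines numbered 2294, of which 2038 changed in the same direction, 760 higher and 1278 lower.

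SERPINH1, the gene with the lowest adjusted p in A375, lies on the lower chromosome 11, but its fall was far larger than that of its surroundings. The 13 tested protein-coding genes within 1 Mb of it had a median log2 fold change of -0.36 and ranged from -0.73 to 0.10, against -5.05 for SERPINH1.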
